A study of Pogostemon cablin with 2 samples.

How the data were processed

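Single-cell RNA libraries were made from protoplasts of globular and cotyledonic somatic embryos of patchouli, 1 library for each stage, with droplet capture of the 10x Genomics type, per the labels' protocols. Protoplasts were released with cellulase and pectinase, and viability was checked before capture. The deposited files of each library are a sparse matrix, a gene list and a barcode list. The matrix holds raw UMI counts per gene and barcode, written by Cell Ranger 5.0.0 per the file headers. The submitters' processing notes name Cell Ranger, STAR and Seurat without saying what each was used for. The genome build and annotation are not given in the sources used here, and no reference was used. The deposited barcodes form a list already restricted to called cells, with no barcode under 1058 UMIs in the globular or 1060 UMIs in the cotyledonic library, so empty droplets were not analysed here. The gene list has 109332 identifiers and is the same in both libraries. Each identifier stands beside itself in place of a name.

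Group membership came from the tissue label. The rules for filtering, clustering, scaling and naming genes, and most of the alternatives, were fixed before the data were examined. A barcode was kept with at least 500 detected genes, at least 1000 UMIs, and no more than 5 median absolute deviations above the median log10 UMIs of its library. The minimum removed 3 globular and 0 cotyledonic barcodes. The upper limit removed 599 and 674, which left 79.9% and 81.0% of the UMIs, or 49413586 and 42860054. The highest totals kept were 14887 and 10803 UMIs. No filter on organelle transcripts was applied, because the files do not say which identifiers are of that kind.

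Doublets were scored in each library with Scrublet through scanpy 1.11.5. Its automatic thresholds of 0.359 and 0.370 marked 1 of 15939 globular and 0 of 16156 cotyledonic cells. This is under the 0.5% below which the method was taken not to have worked, so no cell was removed and doublets remain in the data.

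For levels, counts were summed over the kept cells of each library and scaled by the library sum to give CPM. The log2 fold is that of the cotyledonic over the globular CPM after adding 1 CPM to both, which understates folds of low genes. Ratios are of the CPM without that addition, with exact conditional binomial (Clopper-Pearson) 95% intervals. Sums have exact Poisson and shares have exact binomial intervals. These cover counting error only, and cells were not treated as replicates. Counts of genes past 2-fold use genes at 10 CPM or more in at least 1 library. Named identifiers were the 2 with the largest and the 2 with the lowest log2 fold among the 3675 with at least 50 CPM in 1 library and at least 100 UMIs over both, which is the rule set for identifiers without names. Trimmed mean scaling used edgeR 4.0.16 in R 4.3.3.

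For clusters, both libraries were merged without integration. Genes detected in at least 10 cells were kept, counts were scaled to 10000 per cell and log transformed, and 2000 highly variable genes were scaled with clipping at 10. Principal components (30), a graph of 15 neighbours and the Leiden method (leidenalg 0.10.2, resolution 0.5, seed 0) followed, with umap-learn 0.5.12 for graph weights, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and Python 3.11.15. Genes defining a cluster were ranked by its CPM over the mean CPM of the other clusters, with 10 CPM added to both, and are given as counts only. A cluster was taken to have a counterpart in another clustering when the shared cells were at least 0.5 of the cells in either. Values within clusters were compared where both libraries had at least 50 cells. For genes per cell across depths, each cell was thinned to 2000 UMIs and shallower cells were left out. Figures were drawn with matplotlib 3.10.9.

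The steps were tested on simulated data. For the library sums, with 200 genes changed, 99% of genes with a fold of 4 and 97% of genes with a fold of 2.4 were called at 2-fold in the right direction. Of 16179 unchanged genes at 10 CPM or more, 0 were called, and 94.9% of intervals held the true ratio. Both simulated libraries were Poisson counts from the summed profile of the real ones. These values therefore cover counting error only, and the 0 is no rate of false calls for the real libraries. For the clustering step, 6000 simulated cells drawn from 14 profiles over 109332 genes gave 12 clusters with an adjusted Rand index of 0.906. Without the cells of profiles 1 and 2 the index was 0.986. The profiles were the sums of the reported clusters, and cells of a profile varied by counting only. These indices therefore do not measure how stable the real clusters are. In the real cells another seed alone gave an index of 0.477 with the reported clusters. Cells drawn from 1 profile gave 2 clusters, so a split between similar large clusters can arise without a difference.

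The alternatives concerned scaling, pseudocount, level floor, cell filter, thinning, resolution, number of variable genes, scaling within library and seed. Those added after seeing the data were clustering without the genes at least 1.5-fold apart, cells with at least 2000 UMIs without thinning, leaving out the 10% of cells with the highest doublet scores, thinning all kept cells to 1000 UMIs, clustering without the 1478 genes whose mean log2 ratio within clusters 3 to 9 was at least 1.5-fold, clustering without as many random genes matched on level, leaving out clusters 1 and 2, and equal cluster weights. Equal cluster weights means that both libraries were given the globular library's UMI shares over the clusters. The clusters were made without integration and may be set in part by genes that differ between the libraries. Equal weights would then lower differences between the libraries without a difference in the makeup of cells. Fixed gene lists and cell type markers were not evaluated because no names are paired with the identifiers.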

Results

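The data describe somatic embryos of patchouli (Pogostemon cablin), an aromatic plant of the mint family whose leaf oil is rich in the sesquiterpene patchouli alcohol. Somatic embryos form in culture from cells that are not egg or sperm. They pass through a round, globular stage before the seed leaves, or cotyledons, become visible. Walls were removed by enzymes and single protoplasts were captured in droplets, so that each transcript carries a cell barcode and a unique molecular identifier (UMI). The series has 2 libraries, 1 from globular and 1 from cotyledonic embryos. With 1 library per stage, no difference between the stages has a replicate check, no test was made, and every interval below covers counting error only.

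The globular library held 16541 barcodes with 61879916 UMIs, and the cotyledonic library held 16830 barcodes with 52938844 UMIs. The median barcode had 1789 UMIs and 1425 detected genes in the globular library, against 1664.5 UMIs and 1276 genes in the cotyledonic library. No deposited barcode had fewer than 1058 UMIs in the globular or 1060 UMIs in the cotyledonic library, and 39.4% and 43.5% of barcodes had fewer than 1500. After filtering, 15939 globular and 16156 cotyledonic cells remained, with medians of 1728 and 1606 UMIs. Detected genes per kept cell had a median of 1383 in the globular and 1236 in the cotyledonic library. In cells with at least 2000 UMIs, the medians were 2835 and 2559 genes. When those same cells were thinned to 2000 UMIs each, the medians were 1534 and 1486 genes, over 6807 globular and 6410 cotyledonic cells, with 9132 and 9746 shallower cells left out.

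**Figure D1:**
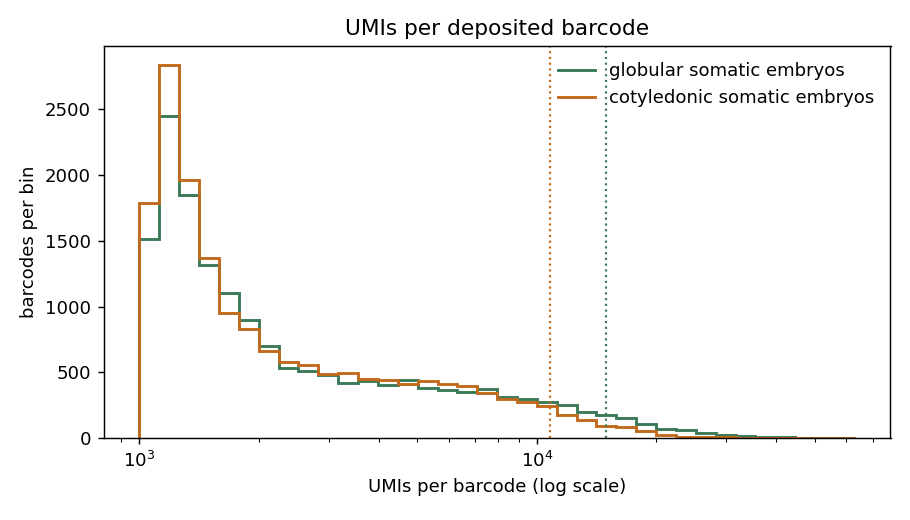
UMIs per deposited barcode (x axis, log scale) against the number of barcodes per bin (y axis) in the globular and cotyledonic libraries, with dotted lines at the highest UMI total kept in each library, 14887 and 10803. Both libraries peak just above their lowest totals of 1058 and 1060 UMIs and have long tails of deeper barcodes.

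The first comparison asked how the level of each gene differed between globular and cotyledonic embryos. The library sums were alike for most genes. Of 17172 genes at 10 CPM (UMIs scaled to a common library total) or more in at least 1 library, 90.6% lay within 1.5-fold between the stages. At least 2-fold higher levels in the cotyledonic library were found for 268 genes, and at least 2-fold lower levels for 212. At 4-fold the counts were 6 higher and 2 lower. These counts use levels with 1 CPM added to both libraries, so a gene can have a plain ratio past a limit without being counted, as Pat_B27G123300 does at 4-fold. None of the genes at 10 CPM or more in 1 library lacked a UMI in the other. Across genes, which are not independent replicates, the log2 levels of the 2 libraries had a Pearson r of 0.959, and the Spearman rho of the levels was 0.927.

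The most abundant identifier was the same in both libraries. It took 1.73% of UMIs in the globular and 3.58% in the cotyledonic library, a ratio of 2.07 (95% exact interval 2.07 to 2.08). The 10 most abundant genes of each library took 4.33% of the globular and 7.03% of the cotyledonic UMIs, and 7 genes were shared between these lists. The median log2 fold of the genes at 10 CPM or more was -0.11 with scaling by library total and -0.02 with trimmed mean scaling.

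The gene identifiers are not paired with gene names in the sources used here, so the pathway lists and cell type markers fixed beforehand, among them the patchouli alcohol pathway and the transcription factor NAC048 named in the title of the series, were not evaluated. Only the extremes fixed by rule are named. Pat_B12G014000 had the largest fold: 449 UMIs (95% Poisson interval 408 to 493) or 9.09 CPM in the globular library, against 2497 UMIs (2400 to 2597) or 58.3 CPM in the cotyledonic library. Its log2 fold was 2.55, a ratio of 6.41 (5.80 to 7.11). Pat_B24G102800 was at 18.4 CPM (910 UMIs, 852 to 971) in globular and 93.8 CPM (4020 UMIs, 3897 to 4146) in cotyledonic embryos, a log2 fold of 2.29 and a ratio of 5.09 (4.74 to 5.48). In the other direction, Pat_B27G123300 was at 68.6 CPM (3388 UMIs, 3275 to 3504) in globular and 16.9 CPM (725 UMIs, 673 to 780) in cotyledonic embryos. Its log2 fold was -1.96 and its ratio 0.247 (0.227 to 0.267). Pat_B07G153100 was at 99.2 CPM (4903 UMIs, 4767 to 5042) and 27.6 CPM (1183 UMIs, 1117 to 1252), a log2 fold of -1.81 and a ratio of 0.278 (0.261 to 0.297).

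**Figure D2:**
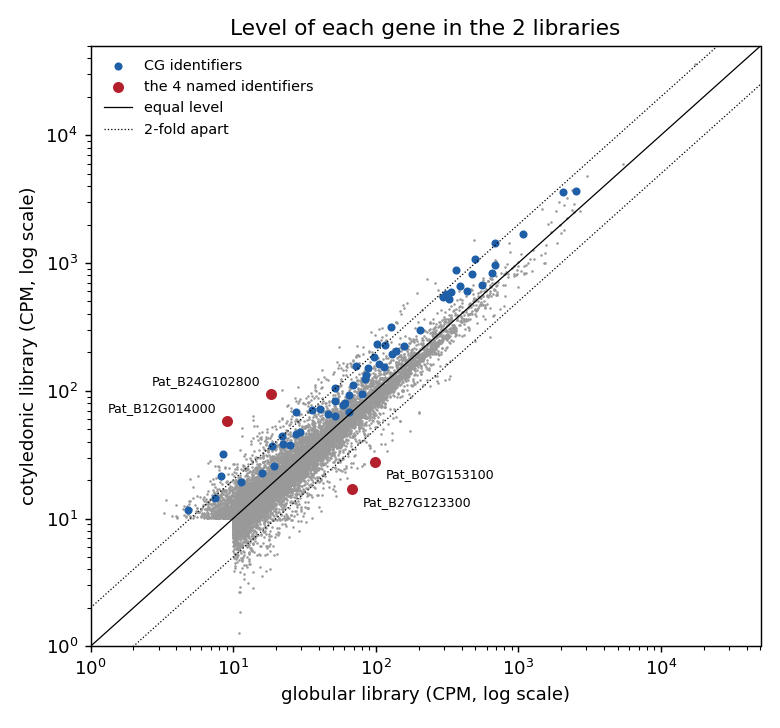
Level of each gene at 10 CPM or more in at least 1 library, in the globular (x axis) and cotyledonic library (y axis), in CPM on log scales, with lines at equal level and 2-fold apart. Blue points are the 56 CG identifiers, all above the line of equal level, and red points are the 4 named identifiers, with Pat_B12G014000 at 9.09 and 58.3 CPM.

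The second comparison asked how the cells of the 2 stages were distributed over clusters of like cells. Clustering the 32095 kept cells of both libraries gave 14 clusters, numbered by size. None had 90% or more of its cells from 1 library after the libraries were weighted equally. This depended on the settings: under some alternatives 1 cluster did, among them another seed alone, resolution 1.0 and 4000 variable genes. Clusters 5, 6, 9, 11, 12, 13 and 14 each had at least 181 genes at 4-fold or more above the mean of the other clusters, and cluster 14 had 1294. Cluster 1 had 18 such genes and cluster 2 had 0. These 2 largest clusters together held 49.0% of globular and 56.0% of cotyledonic cells, with median totals of 1410 and 1369 UMIs per cell. Clusters 4, 6 and 9 had similar medians of 1480, 1459 and 1567 UMIs but 122, 240 and 182 genes at 4-fold or more, while clusters 3 and 5 were deeper, at 4129 and 4238 UMIs.

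Cluster 1 held 10.6% of globular cells (95% Clopper-Pearson interval 10.1 to 11.1) and 46.4% of cotyledonic cells (45.6 to 47.2). Cluster 2 held 38.4% (37.7 to 39.2) and 9.55% (9.10 to 10.0). The ratios of 4.39 and 0.249 depended on the settings. That of cluster 1 was 6.85 at resolution 1.0, where its cotyledonic share was 28.3%, and 3.41 without the 10% of cells with the highest doublet scores, where that share was 26.6%. That of cluster 2 was 0.0825 with 4000 variable genes, 0.102 with another seed and 0.496 at resolution 0.2. Of the top 10 defining genes, 10 in cluster 1 and 7 in cluster 2 were at least 1.5-fold apart in the library sums, which move with the cluster shares, and clusters 6, 8, 12 and 13 had 8, 7, 8 and 7 such genes. Within the cluster, 1 of the 10 in cluster 1 and 0 in cluster 2 were 2-fold apart between the libraries, with median log2 folds of 0.26 and 0.23. The share of cells that would have to change cluster to equalise the libraries, the composition distance, was 40.8%. It was 13.5% when the cells were clustered again without the 3698 genes at least 1.5-fold apart, and 12.8% when values were scaled within each library. In neither reclustering did cluster 1 or cluster 2 have a counterpart, but cluster 1 also had none with another seed alone or with 1000 or 4000 variable genes.

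Cluster 12 held 0.282% of globular (0.206 to 0.378) and 0.712% of cotyledonic cells (0.588 to 0.854), a ratio of 2.52. Without the genes at least 1.5-fold apart, its counterpart had a ratio of 2.41. Cluster 11 held 0.991% (0.843 to 1.16) and 0.402% (0.311 to 0.513), a ratio of 0.406, and its counterpart had 0.529 without those genes and 0.637 in cells thinned to 2000 UMIs. Cluster 4 held 8.90% (8.47 to 9.36) and 7.11% (6.71 to 7.51), a ratio of 0.798. This was 0.690 without those genes, 0.570 in cells thinned to 2000 UMIs and 0.822 when scaled within each library. Cluster 5 held 8.90% and 6.19% (5.82 to 6.57), a ratio of 0.695, against 0.838 without those genes, 0.522 at resolution 0.2 and 0.413 with 1000 variable genes. Cluster 8 held 6.53% (6.15 to 6.93) and 2.12% (1.91 to 2.36), a ratio of 0.325, but had no counterpart when those genes were left out. Cluster 6 held 5.84% (5.48 to 6.22) and 5.76% (5.41 to 6.13), a difference within counting error in this clustering. Its ratio of 0.987 was 0.866 at resolution 0.2, 0.846 with 1000 variable genes and 0.853 without those genes. It was 1.02 at resolution 1.0 and with another seed.

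**Figure D3:**
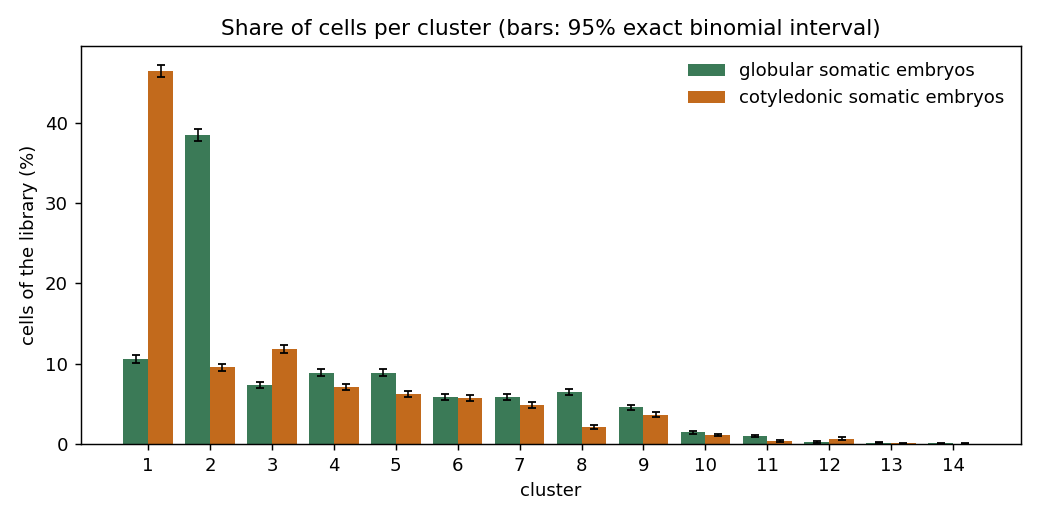
Percent of the cells of each library (y axis) in each of the 14 clusters (x axis), with bars for the 95% exact binomial interval. Cluster 1 held 10.6% of globular and 46.4% of cotyledonic cells and cluster 2 held 38.4% and 9.55%, while the shares of most other clusters were closer.

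The level of each named identifier was then compared within clusters. In 11 clusters with at least 50 cells from each library, Pat_B12G014000 was higher in cotyledonic cells with an interval above 1 in 10, with ratios from 2.59 to 10.3. Pat_B24G102800 also had an interval above 1 in 10 clusters. Its ratio in cluster 11 was 1.02 (0.175 to 4.26), so no difference was detectable there. Pat_B27G123300 and Pat_B07G153100 were lower in cotyledonic cells in all 11 clusters, with ratios from 0.133 to 0.539 and from 0.0368 to 0.592. The lowest of these, for Pat_B07G153100 in cluster 11, rests on 1 cotyledonic UMI (interval 0.0009 to 0.212). The named identifiers were picked by their folds in the sums of these same cells. A shared direction over the clusters is therefore set in part by that choice. With the clusters of both libraries given the weights of the globular library, the ratios were 4.18, 3.05, 0.310 and 0.430, in the order named.

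Levels of the named identifiers also differed between clusters of the same library. In cotyledonic cells, Pat_B12G014000 was at 113 CPM (108 to 119) in cluster 1 and 18.4 CPM (15.6 to 21.6) in cluster 3. Pat_B24G102800 was at 193 CPM (186 to 201) in cluster 1 and 212 CPM (173 to 256) in cluster 10, against 25.3 CPM (22.0 to 29.0) in cluster 3. Cluster 3 is deeper, and per barcode its cotyledonic cells were closer to those of cluster 1 than in CPM. The means in clusters 1 and 3 were 0.221 and 0.0791 UMIs for Pat_B12G014000 and 0.378 and 0.109 for Pat_B24G102800. Cluster 1 gave 66.3% and 70.5% of the cotyledonic UMIs of these 2 identifiers. In globular cells, Pat_B27G123300 reached 556 CPM (500 to 618) in cluster 11 and 154 CPM (145 to 164) in cluster 5, against 17.1 CPM (13.4 to 21.5) in cluster 1. The cotyledonic cells of clusters 11 and 5 had 151 and 20.5 CPM of it. Pat_B07G153100 was at 184 CPM (172 to 196) in globular cells of cluster 7, 153 CPM (146 to 160) in cluster 2 and 36.8 CPM (29.0 to 46.1) in cluster 9. In cotyledonic cells it was at 90.4 CPM (81.3 to 100.3) in cluster 2 and 7.29 CPM (4.98 to 10.3) in cluster 5.

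**Figure D4:**
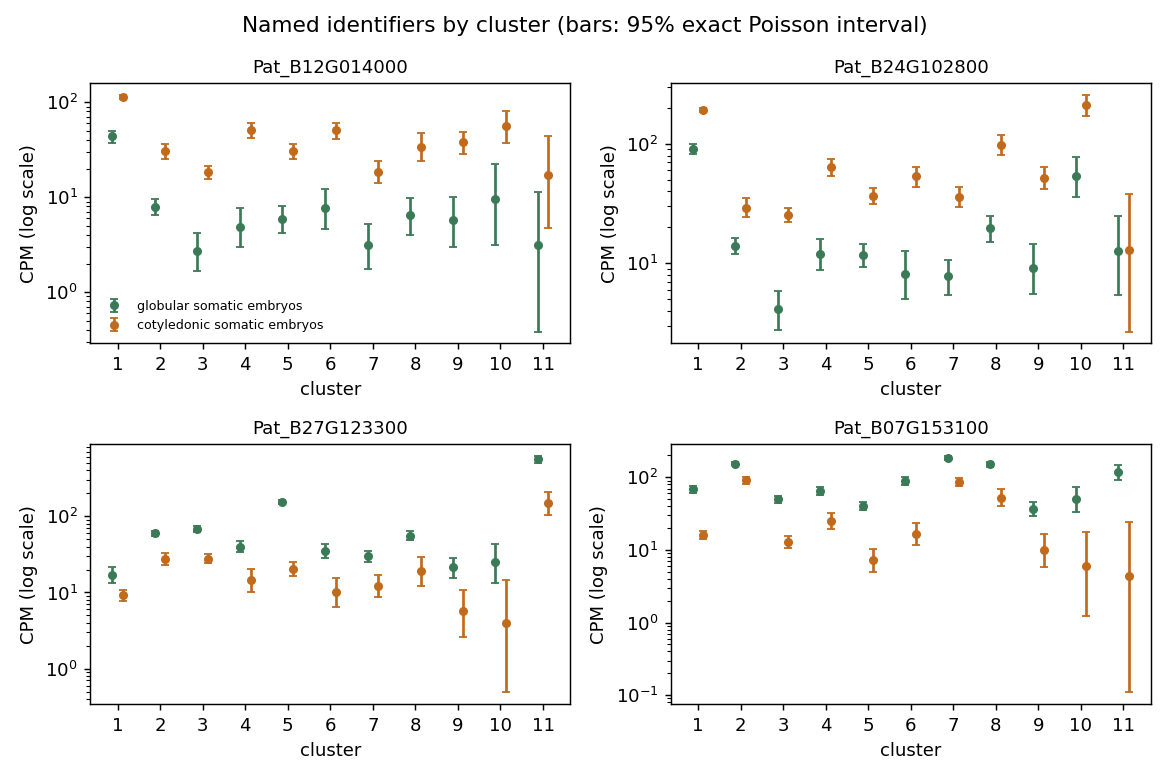
Level of the 4 named identifiers (y axis, CPM, log scale) in clusters 1 to 11 (x axis) of the globular and cotyledonic libraries, with bars for the 95% exact Poisson interval. Pat_B12G014000 was at 113 CPM in cotyledonic cells of cluster 1, and Pat_B27G123300 at 556 CPM in globular cells of cluster 11.

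The third comparison set groups of identifiers side by side. After the species tag, identifiers carry the letters A (57276 identifiers), B (49881), U (2096) or CG (79). What the letters stand for is not given in the sources used here. The CG identifiers took 1.43% of globular and 2.33% of cotyledonic UMIs, a ratio of 1.63. The median share per cell was 0.868% in globular and 2.13% in cotyledonic cells. All 56 CG identifiers at 10 CPM or more were higher in the cotyledonic library, with a median log2 fold of 0.70. The U identifiers took 2.13% and 4.14% of UMIs, most of it from the most abundant identifier of both libraries, and their median log2 fold at 10 CPM or more was 0.14. Of the UMIs on A and B identifiers, A took 53.4% in the globular and 53.6% in the cotyledonic library. The counting intervals of these shares were narrower than the last digit or close to it.

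By cluster, the CG share was higher in cotyledonic cells in 9 of 11 clusters, by 0.314 to 1.26 percentage points. In cluster 4 it was 1.09% (1.08 to 1.1) in globular and 2.30% (2.28 to 2.32) in cotyledonic cells, and in cluster 6 it was 1.24% and 2.50%. Cluster 1 had a high share in both libraries, 3.26% (3.25 to 3.28) and 3.25% (3.24 to 3.26), with no difference beyond counting error. These are shares of the summed UMIs. The median share per cell in cluster 1 was 3.13% in globular and 2.79% in cotyledonic cells. Cluster 10 stood apart with 29.9% (29.8 to 30.1) in globular and 22.6% (22.5 to 22.8) in cotyledonic cells. However, cluster 10 had no counterpart in any alternative clustering planned beforehand, among them another seed alone. It had one under some of those added after seeing the data. With both libraries given the cluster weights of the globular library, the ratio of their CG shares was 1.29.

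**Figure D5:**
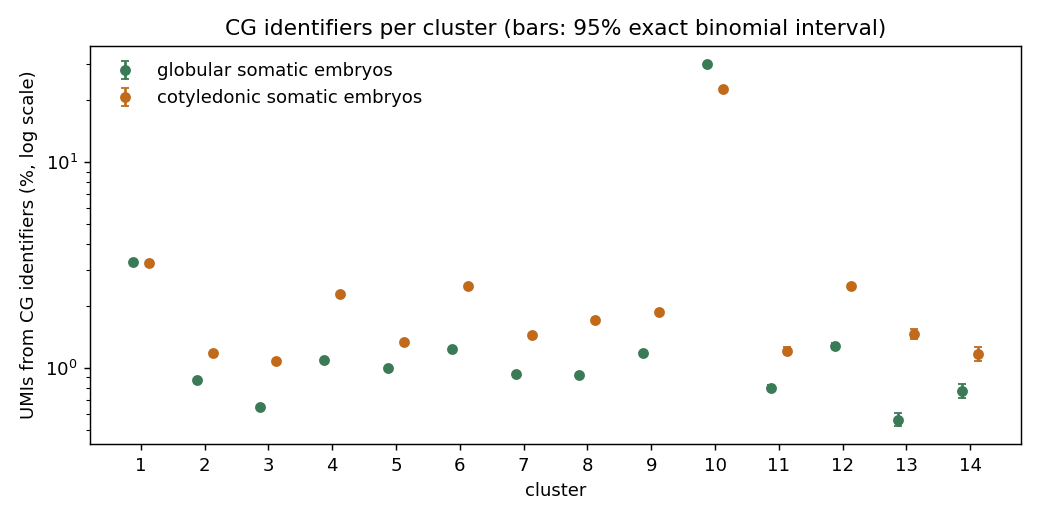
Percent of UMIs from CG identifiers (y axis, log scale) in clusters 1 to 14 (x axis) of each library, with bars for the 95% exact binomial interval, most of them smaller than the points. Cluster 10 lies at 29.9% in globular and 22.6% in cotyledonic cells, and cluster 1 at 3.26% and 3.25%.

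The counts of genes past 2-fold depended on the weights of the clusters, the floor and the pseudocount. With each cluster weighted as in the globular library, 84 genes were at least 2-fold higher and 104 at least 2-fold lower, so that higher genes made up 44.7% of the calls in place of 55.8%. Of the 268 higher and 212 lower genes, 72 and 94 were still 2-fold apart under those weights. Where genes that differ between the libraries set the clusters, equal weights would lower such counts without a difference in the makeup of cells. With a pseudocount of 10 CPM the counts were 135 and 57, of which higher genes were 70.3%. With a floor of 50 CPM they were 141 and 60, and with no floor 419 and 377. Without the cells of clusters 1 and 2, lower genes were the majority, with 203 higher and 233 lower.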

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

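The tests of Pat_B12G014000 and Pat_B24G102800 in this part were chosen only after the result was seen, and equal cluster weights, clustering without the genes at least 1.5-fold apart, the unthinned cells with at least 2000 UMIs, thinning all kept cells to 1000 UMIs and clustering without genes that differ within clusters 3 to 9 were added after seeing the data. For the tests of these identifiers and the CG test by cluster, the requirement that a value lie beyond its limit by more than its counting interval was also applied only after the values were seen. Without it, the result for Pat_B12G014000 would have counted for free RNA. The CG result, for an equal added share, and that of Pat_B24G102800 without cluster 10 would have counted against it.

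The CG share in cluster 10 was -7.28 percentage points in cotyledonic minus globular cells (29.9% and 22.6%), while it was higher by 0.314 to 1.26 points in 9 of the 11 clusters compared. It stood out because the direction was opposite to those clusters. Cluster 10 had no counterpart with another seed alone, so the value holds for the reported clustering. The difference between clusters was not tested.

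The larger CG share of the cotyledonic library does not rest on a few identifiers, since 100% of the CG identifiers at 10 CPM or more were higher there. Unequal cluster makeup may carry part of it. With both libraries given the cluster weights of the globular library, the ratio was 1.29 in place of 1.63. This lay between the limits set for and against that explanation. The fall cannot be credited to the makeup of cells, because genes that differ between the libraries may have set the clusters in part. Equal weights would then lower the ratio in any case. The cotyledonic weights were not tried. Under them cluster 1 would count more, and its pooled CG share did not differ beyond counting error. Free RNA adding the same CG share to every cluster was not settled either. The largest difference was 4.03 times the smallest, just past a limit of 4, but its lower limit from counting was 3.81. Clusters 1 and 10 had no higher share. These values cannot decide on free RNA that adds a similar number of UMIs to every barcode. Such UMIs would change the share less in deeper clusters and would lower a CG share above their own. Developmental stage remains open and untested with 1 library per stage.

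Clusters 1 and 2 were filled unequally by the 2 libraries. Unequal UMIs per cell are argued against as the whole cause because the composition distance stayed at 0.881 of its value with every kept cell thinned to 1000 UMIs (0.986 after thinning to 2000 UMIs, in deeper cells where clusters 1 and 2 have no counterpart and which decide nothing). Free RNA in barcodes near the UMI minimum stays open: genes that define clusters 4, 6, 9, 12 and 14 had a median level in clusters 1 and 2 of 0.323 of that in the whole library, with 0.0786 to 0.500 by cluster, but this assumes that free RNA has the profile of the kept cells, and empty droplets were not analysed here. Genes that differ between the libraries in many kinds of cell also stay open: leaving out those apart in the library sums brought the distance to 0.331 of its value, and leaving out 1478 apart within clusters 3 to 9 to 0.227 of that without as many random genes, but the genes were chosen for differing between the libraries, 1212 of the 1478 were apart in the sums too, and clusters 1 and 2 had no counterpart in either case. Stage and preparation cannot be told apart with 1 library per stage.

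Pat_B12G014000 and Pat_B24G102800, picked for their folds in the sums of these same cells, were higher in cotyledonic cells of 10 of 11 clusters. Free RNA that adds the same number of UMIs to every barcode would give similar means over clusters 2 to 10. The highest and lowest clusters were picked from the data, which raises their ratio and which the intervals do not allow for. For Pat_B12G014000 the highest mean was 1.96 times the lowest (1.2 to 3.11), which leaves that source open. For Pat_B24G102800 it was 7.47 times (5.68 to 9.81), which argues against equal addition in all of these clusters but rests on cluster 10, the highest of them in globular cells too; without it the ratio was 4.15 (3.16 to 5.44), which leaves free RNA open in the other clusters. Free RNA of Pat_B27G123300 and Pat_B07G153100 in the globular library was not tested. Developmental stage was not tested against other differences between the libraries.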

How the results depend on the processing

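The alternatives without clusters 1 and 2, with equal cluster weights, without the highest doublet scores, without genes at least 1.5-fold apart (library sums, or within clusters 3 to 9), without random genes, with at least 2000 UMIs unthinned and with all cells thinned to 1000 UMIs were chosen after seeing the data. The causes of the shifts were not tested, except that a floor or pseudocount by construction changes how many genes can pass. Genes at least 2-fold higher and lower (268 and 212) were 135 and 57 with a pseudocount of 10 CPM, 419 and 377 with no floor, 141 and 60 with a floor of 50 CPM, and 84 and 104 with equal cluster weights. Under the other alternatives both counts stayed within 1.5 times, but the balance shifted, to 327 and 174 with TMM scaling (65.3% higher in place of 55.8%) and to 203 and 233 without clusters 1 and 2. The 4 named identifiers kept their direction in every alternative run. With a pseudocount of 10 CPM the log2 fold of Pat_B24G102800 (1.87) was above that of Pat_B12G014000 (1.84), so their order turned. The composition distance (40.8%) was 39.2% at resolution 0.2, 30.1% and 43.7% with 1000 and 4000 variable genes, 12.8% scaled within library, 23.7% in thinned cells, 22.4% with at least 1000 genes and 2000 UMIs, 24.1% with at least 2000 UMIs unthinned, 13.5% without genes at least 1.5-fold apart in the library sums, 9.65% without those apart within clusters 3 to 9, 42.6% without as many random genes, 35.9% with all cells thinned to 1000 UMIs and 35.9% without the highest doublet scores. The share of cluster 3 (ratio 1.61) turned to 0.995 with 4000 variable genes and 0.968 with seed 1. That of cluster 9 (0.802) turned to 1.06 in thinned cells, 1.08 with at least 1000 genes and 2000 UMIs and 1.13 with at least 2000 UMIs unthinned. That of cluster 10 (0.788, exact interval 0.647 to 0.960) turned to 1.77 in the last of these and to 1.18 with all cells thinned to 1000 UMIs. The CG ratio (1.63) was 1.72 without the 100 most abundant genes, 1.67 over all barcodes and 1.29 with equal cluster weights. The difference in the A share of A and B (0.243 points) was 0.144 without the 100 most abundant genes and 0.159 with equal cluster weights. Another seed alone gave an adjusted Rand index of 0.477 with the reported clusters. Of the other values of single genes, clusters and depth under each alternative, 61 moved beyond counting error without turning and 122 did not. The 122 include the log2 folds of the named identifiers under other floors, which a floor cannot change. Keeping doublets changed nothing because none was removed, and the fixed gene list alternatives were not run for lack of names. Clusters without a counterpart gave no value and are in neither count, among them cluster 10 under every alternative clustering planned beforehand. The counts are therefore no measure of how stable the clusters are. No paired analysis was possible because each stage has 1 library. Few cells limit the smallest cluster, with 22 and 14 cells in cluster 14.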

Other observations

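Within clusters, levels in the 2 libraries lay close together for the most part. Among genes with at least 200 UMIs in the cluster, the spread of log2 ratios beyond counting error had an SD of 0.29 in cluster 1 and 0.28 in cluster 2. It was larger in cluster 9 (0.60), cluster 10 (0.55), cluster 11 (0.54) and cluster 5 (0.48). Cluster 7, with 0.31, was among the closest. The SDs cover different genes, 15255 in cluster 1 and 13873 in cluster 2 but 343 in cluster 10 and 579 in cluster 11. The clusters are therefore not strictly comparable. Genes are not independent replicates, and with 1 library per stage the spread between libraries of the same stage is unknown.

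Genes at least 2-fold higher in the cotyledonic library were 142 A, 114 B, 11 CG and 1 U identifier, and those at least 2-fold lower were 121 A and 91 B identifiers. Over the 32 A and 31 B number blocks, the ratio of UMI shares ranged from 0.873 to 1.19. Cells with at least 10% of UMIs on CG identifiers made up 2.01% of globular and 2.28% of cotyledonic cells.

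The following test was chosen only after the result was seen. A hypothesis was that A and B blocks with the same number hold paired gene copies, so that an A gene and the B gene with the most similar profile over 422 groups of like cells would often share a number. They did so for 7.09% of 7854 A genes, against 3.39% by chance, a ratio of 2.09 that lay between the limits set for and against the hypothesis. With shuffled B numbers the ratio was 0.94. Among the 1277 A genes with a best correlation of 0.5 or more, 17.8% shared the number and 10.9% had the neighbouring number of a pair. The neighbouring number was also above chance over all A genes, 5.50% against 3.44%, which weakens the reading that the same number marks the copy. Going with the hypothesis, the identifier order of same-number pairs had a median Spearman rho of 0.419 over the numbers, with a lowest of 0.175 and a highest of 0.660. This covered 11 numbers with 20 or more pairs, and no shuffled comparison was made for it. The blocks may hold such copies. Whether reads shared between similar copies add to the likeness of the profiles was not tested.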
